A study of Rattus norvegicus with 6 samples.

How the data were processed

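Primary endothelial cells of the rat (Rattus norvegicus) abdominal aorta were profiled by full-length transcriptome sequencing in 6 libraries, 3 of wild-type cells (WT) and 3 of cells whose genotype label names a knockdown of the microRNA miR-337-3p (KD). Per the labels' protocols, cells were grown on fibronectin in endothelial medium, total RNA was column-purified, and full-length cDNA was reverse transcribed and amplified with few PCR cycles. The labels differ in how they describe the perturbation. The sample titles and the series design speak of a knockout, the genotype field of a knockdown, and the treatment protocol, which is worded identically for WT and KD libraries, of transfection with 100 nM of an inhibitor of the human miR-337-3p. What the WT cells received is therefore not settled by the labels, and the groups were taken as labelled.

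The deposited table holds estimated counts per gene, not normalized, for 32879 rows and 6 libraries. Of its values 21.6% are not whole numbers, judged on the printed value with a tolerance of 0. This share is over all rows of the file. Of the 12852 rows tested below, only 2490 held whole numbers in all 6 libraries, before that subset was filtered anew for its own test. Values are printed with at most 6 significant digits, so the 1 row that reaches 100000 counts shows no decimals and is taken as whole. Rows carry either a rat Ensembl gene identifier (30560 rows) or a numbered identifier of the submitters' own for a gene model outside Ensembl (2319 rows, called non-Ensembl models here), which the file defines no further. Per the submitters' processing notes the genome build was mRatBN7.2. The aligner, the counting tool, their versions and the strand setting are not given in the sources used here. Fractional counts arise where a counter divides a read among features, so rows that overlap or resemble each other, paralogs included, can exchange reads, and this cannot be followed per gene here.

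The table gives no gene symbols, and the reference gene list at hand (GRCr8) pairs 0 of its rows with an Ensembl identifier. No genome sequence or 3′ UTR annotation was used. For that reason the 28 gene lists fixed before the data were examined (endothelial identity, other vascular cell types, inflammation, cell cycle and others) and the test of genes with sites for 3 versions of the miR-337-3p seed were not run. Levels of the miR-337 host locus, of reported targets, and of mitochondrial, ribosomal protein and haemoglobin genes are not analysed here, nor are positions. The rule for named genes was limited to the 2 Ensembl identifiers with the largest fitted rise and the 2 with the largest fitted fall. Eligible rows had to pass the threshold, have no overlap between the 3 WT and 3 KD libraries, and have a mean CPM of at least 10 in the higher group. Under this rule 874 risen and 887 fallen Ensembl rows were eligible. The 3 most abundant rows are described by rank.

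Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood F test, model with group alone), with Benjamini-Hochberg adjustment over all 12852 tested rows and a threshold of 0.05. Standard errors of log2 fold changes are approximations, the size of the log2 fold change divided by the square root of F. They can be smaller than counting error alone where 1 group holds few counts. Named rows with few counts in 1 group are therefore given with a count interval instead. Values per library are given as CPM, the count divided by the library total and scaled in the usual way. Library totals and other composition measures were compared by two-sided exact permutation tests over 20 arrangements, whose smallest possible p is 0.1. Intervals of count ratios are 95% exact (Clopper-Pearson) intervals, which cover counting error only, as no molecular identifiers are described. They treat the rounded estimates as observed reads. On counts simulated for the KD against WT comparison, with 200 rows changed, edgeR tested 12671 rows and recovered 64.6% of changes of 1.5-fold, 87.9% of 2-fold and 98.5% of 4-fold, with 10 false calls among 174. DESeq2, given all 12852 simulated rows, recovered 43.3%, 62.7% and 93.9%, with 1 false call among 134, and limma-voom on 12671 rows 64.6%, 84.8% and 100%, with 9 among 172. The simulation drew each row at the dispersion of the abundance trend, without a spread particular to the row or an outlying library. It also changed far fewer rows than were called in the data. These rates therefore need not hold for the real comparison.

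Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE, upper quartile and library-size scaling, no count filter or a mean count of at least 50, an adjusted p of 0.01, a fold of at least 2, a replicate block and leaving out each library. Restriction to rows with whole counts, to Ensembl rows, and removal of the 10 most abundant rows were added after seeing the data. A correction for gene length was not run. No separate cultures or animals are named, so p-values measure the spread between these libraries, which may be technical. Within-group pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 2.03 to 5.92, rows with at least 20 counts), so all were kept as separate samples. The value was higher in pairs with WT replicate 3 (3.37 and 4.49) or KD replicate 1 (3.92 and 5.92). In the pairs without these libraries it was 2.03 for WT and 2.2 for KD. Deviations from the group means did not correlate between equally numbered WT and KD libraries (r across rows -0.0166, 0.00503 and 0.0361), so the numbers were not treated as pairs.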

Results

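The transcriptome of primary rat abdominal aortic endothelial cells, the cells that line the vessel, was measured in 3 WT and 3 KD libraries to map expression differences between wild-type cells and cells labelled as lacking or reduced in miR-337-3p. A microRNA represses messenger RNAs through base pairing. Total estimated counts lay between 5037127 and 5385434 per library, and between 17634 and 17768 rows had a count above 0. The mean total was 5154990 ± 123597 (SD, n = 3) in KD and 5208080 ± 156443 (SD, n = 3) in WT libraries, a difference smaller than the spread between libraries (two-sided exact permutation test, p = 0.6, adjusted over 5 measures p = 0.9). Non-Ensembl gene models took 4.36% ± 0.349 (SD, n = 3) of KD counts and 4.40% ± 0.0909 (SD, n = 3) of WT counts (exact permutation p = 0.9, adjusted p = 0.9). The number of rows detected was 17693.3 ± 42.6 in KD and 17685.3 ± 72.3 in WT libraries (SD, n = 3 each; exact permutation p = 0.8, adjusted p = 0.9). The file names genes by Ensembl identifier alone, so genes are reported by identifier and by group of rows, and the level of miR-337 itself is not analysed here.

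The libraries separated by group. Spearman correlations across the tested rows were 0.982 to 0.987 within groups and 0.951 to 0.960 between groups. The first principal component carried 65.0% of the variance and placed all 3 KD libraries on one side and all 3 WT libraries on the other. The second component carried 10.5%. The common biological coefficient of variation was 8.4%.

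KD and WT cells differed in the expression of 2730 of 12852 tested rows, which is 21.2%. In KD cells 1409 rows rose and 1321 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Most of these changes were small. The median change among them was 1.63-fold, and 1863 of them, or 68.2%, were below 2-fold. Of the 2730 rows, 93.8% had all 3 libraries of one group above all 3 of the other. Over all tested rows 35.4% were separated in this way on CPM, 1913 with KD above WT and 2633 with KD below, where chance gives 10%. These CPM use library totals without the TMM factors of the calls. Under library-size scaling the median log2 fold change of all rows was -0.05, which adds to the rows with KD below. The balance of rises and falls depended on the scaling: with library size alone in place of TMM factors 1234 rows rose and 1633 fell. DESeq2 called 1042 rises and 842 falls.

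**Figure D1:**
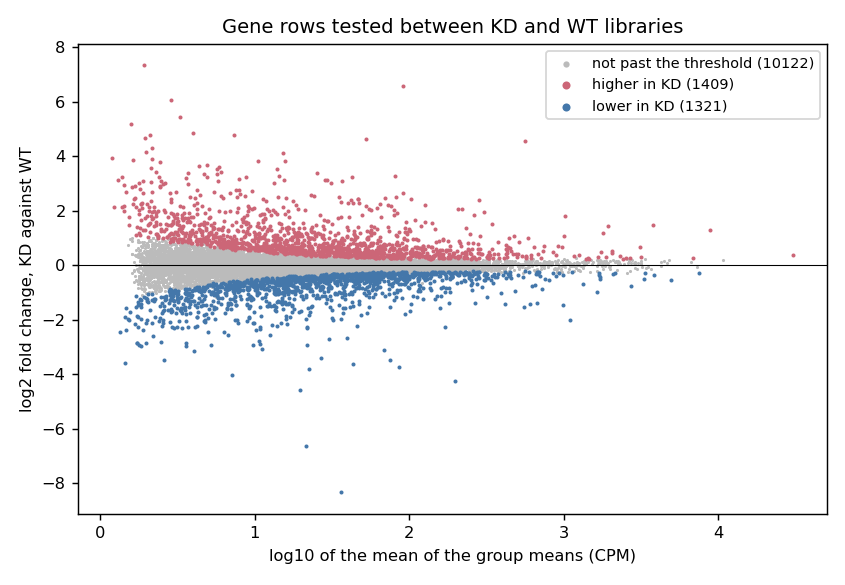
Each point is a tested row, with the log10 of its mean abundance in CPM on the x axis and the log2 fold change of KD against WT on the y axis. Rows past the threshold are coloured by direction (1409 higher and 1321 lower in KD), and they lie over the whole range of abundance.

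Larger changes were more often rises than falls. At least 2-fold, 489 rows rose and 378 fell. At least 4-fold, 152 rose and 78 fell. At least 8-fold, 54 rose and 15 fell, and at least 16-fold, 14 rose and 5 fell. Folds in these classes are fitted values. Of the 54 risen rows 1 had 0 counts in all WT libraries, and it stayed in the class when the WT group was set to a floor of 3 counts. The numbers at 8-fold were 17 rises and 11 falls in rows with a mean count of at least 50, 99 and 44 with no count filter, 83 and 27 with DESeq2, 44 and 8 in Ensembl rows alone, and 22 and 1 in rows with whole counts. With single libraries left out the falls of at least 8-fold numbered 15 to 26. They numbered 24 without KD replicate 1, 26 without KD replicate 3, and 22 without WT replicate 3 or KD replicate 2. Each of these fits filtered the rows anew and tested more of them than the main fit.

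**Figure D2:**
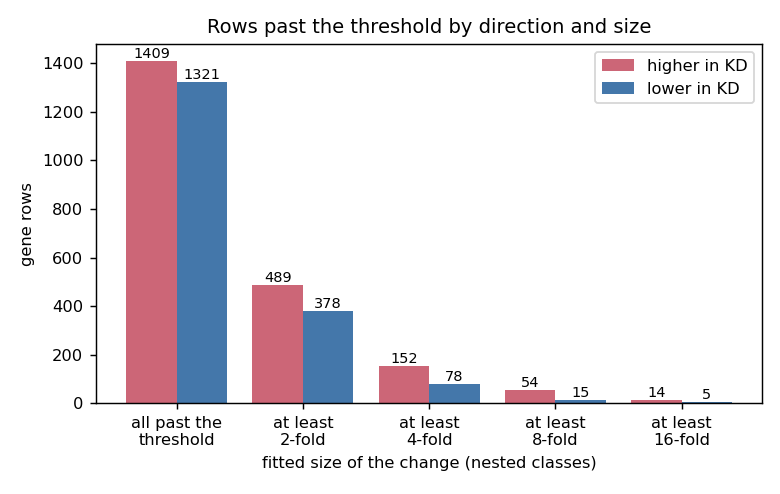
Bars give the number of rows past the threshold that were higher or lower in KD, for all such rows and for nested classes of fitted change of at least 2, 4, 8 and 16-fold. Rises and falls are close in number overall (1409 and 1321) and further apart at 8-fold (54 and 15).

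Among Ensembl rows with no overlap between the groups and a mean of at least 10 CPM in the higher group, ENSRNOG00000032626 had the largest fitted rise. It went from 1.91 ± 0.272 CPM in WT to 179 ± 16.1 in KD libraries (SD, n = 3 each). Its log2 fold change was 6.57 (edgeR adjusted p = 5.4e-18), and it had the smallest p of all tested rows. The WT libraries held 30 rounded counts of it in all and the KD libraries 2767, a ratio of 93.2 with a 95% exact interval of 65.1 to 138. ENSRNOG00000014398 had the next largest rise among the rows so limited, from 0.514 ± 0.228 to 14.2 ± 2.1 CPM (SD, n = 3 each), a log2 fold change of 4.77 (edgeR adjusted p = 1.5e-10). This row rests on 8 WT counts against 219 KD counts, which gives a ratio of 27.7 with a 95% exact interval of 13.8 to 64.9.

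Under the same limits ENSRNOG00000017073 had the largest fall. It went from 72.5 ± 6 CPM in WT to 0.196 ± 0.194 in KD libraries (SD, n = 3 each; edgeR adjusted p = 5.4e-16). Its estimates, rounded to whole counts, were 1, 0 and 2 in the 3 KD libraries, against 400, 343 and 390 in the WT libraries. A rounded 0 can stand for a fraction of a count. The WT to KD ratio was 374, with a 95% exact interval of 128 to 1815. Its fitted log2 fold change of -8.33 depends on the prior count that edgeR adds, and it became -9.19 without KD replicate 3 and -7.79 without KD replicate 2. ENSRNOG00000025711 had the next largest fall under these limits, from 373 ± 16.2 to 19.3 ± 1.68 CPM (SD, n = 3 each), a log2 fold change of -4.23 with a standard error of 0.10 (edgeR adjusted p = 7.3e-18). All 4 identifiers kept their direction and stayed past the threshold in every alternative in which they were tested. ENSRNOG00000014398 was not tested at a mean count of at least 50. Of the 4, it alone was tested among rows with whole counts. The others hold fractional estimates, so an exchange of reads with other rows could not be checked for them.

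**Figure D3:**
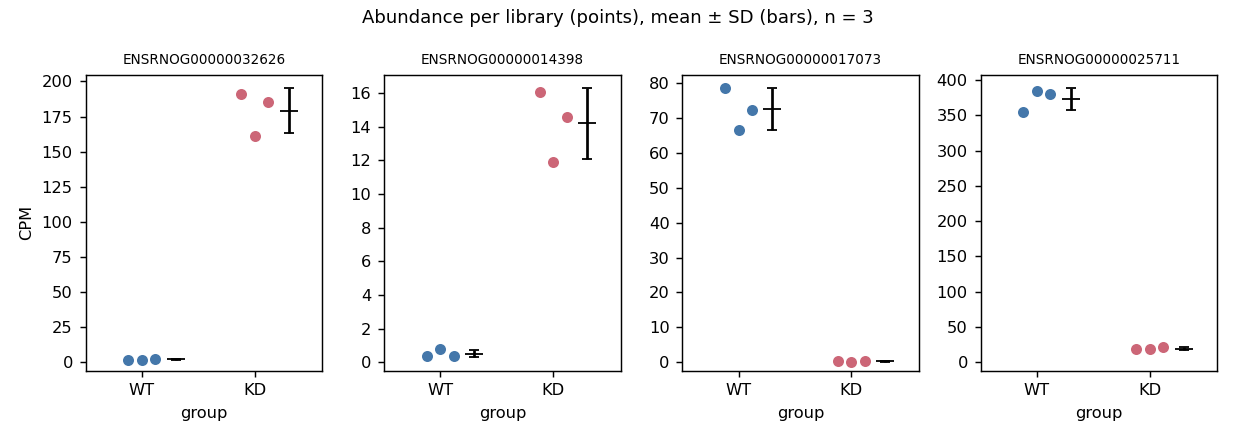
Points give the abundance of each of the 4 named Ensembl rows in each library in CPM, on a linear axis that includes 0, with the mean and SD of the 3 libraries of a group beside them. The 3 KD libraries lie above the 3 WT libraries for ENSRNOG00000032626 and ENSRNOG00000014398 and below them for ENSRNOG00000017073 and ENSRNOG00000025711.

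Changes also reached the most abundant transcripts. Among the 100 most abundant rows 17 rose, 13 fell and 70 did not pass the threshold. The row at abundance rank 3, an Ensembl gene, rose from 5204 ± 262 to 12357 ± 990.0 CPM (SD, n = 3 each), a ratio of 2.37 without TMM factors. Its fitted log2 fold change, with TMM factors, was 1.29 with a standard error of 0.09 (edgeR adjusted p = 2.2e-10). The most abundant row had 27034 ± 874 CPM in WT and 34102 ± 5254 in KD libraries (SD, n = 3 each), a log2 fold change of 0.38 with a standard error of 0.10 (edgeR adjusted p = 0.0095). This call was lost without WT replicate 1 (adjusted p = 0.071), WT replicate 2 (adjusted p = 0.080) or KD replicate 3 (adjusted p = 0.095), with log2 fold changes of 0.34, 0.37 and 0.33. It was also lost when only rows with whole counts were tested (log2 fold change 0.40, adjusted p = 0.14). The call held without WT replicate 3 (edgeR adjusted p = 0.0026), KD replicate 1 (adjusted p = 3.5e-05) or KD replicate 2 (adjusted p = 0.0496). The log2 fold change was 0.51 without KD replicate 1, whose 28142 CPM lay just above the highest WT value of 28015. The row at abundance rank 2 had 10214 ± 314 CPM in WT and 11190 ± 245 in KD libraries (SD, n = 3 each) and did not pass the threshold (edgeR adjusted p = 0.14). The 10 most abundant rows of each library together took 10.1% ± 0.594 of KD counts and 8.62% ± 0.179 of WT counts (SD, n = 3 each; exact permutation p = 0.1, the smallest possible, adjusted p = 0.25). The most abundant row alone took 3.41% ± 0.525 of KD counts and 2.70% ± 0.0874 of WT counts (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.25).

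The only grouping of genes that the file carries is that of Ensembl genes against gene models outside Ensembl. Of 10968 tested Ensembl rows 1151 rose, 1157 fell and 8660 did not pass the threshold. Of 1884 tested non-Ensembl models 258 rose, 164 fell and 1462 did not pass. DESeq2 called 162 rises and 96 falls among these models, and 123 and 74 passed in rows with a mean count of at least 50. At an adjusted p of 0.01 their falls numbered 100. Falls of Ensembl rows numbered 746 with DESeq2 and 724 at an adjusted p of 0.01. Rises made up 61.1% of the non-Ensembl models past the threshold and 49.9% of the Ensembl rows past it, an odds ratio of 1.58 with a 95% interval of 1.27 to 1.97 (two-sided Fisher's exact test across rows, which are not independent replicates, p = 2.2e-05, one comparison). Both shares moved with tool and scaling: they were 62.8% and 54.1% with DESeq2, and 55.4% (229 rises, 184 falls) and 41.0% (1005 rises, 1449 falls) with library size alone. The difference did not pass without WT replicate 2 (58.3% and 52.4%, odds ratio 1.27, Fisher's exact p = 0.058), among changes of at least 2-fold (odds ratio 1.31, Fisher's exact p = 0.12) or in rows with whole counts (odds ratio 1.55, Fisher's exact p = 0.12). It was smaller without KD replicate 2 (57.8% and 50.5%, odds ratio 1.34) and larger without KD replicate 1 (68.9% and 50.7%, odds ratio 2.16). When all 1884 non-Ensembl models were set against all other tested rows, the difference did not pass (limma camera, direction up, p = 0.18 with a preset correlation of 0.01 and p = 0.57 with an estimated correlation). That test asks about all models, called or not. It has little power for so large a set once correlation between rows is allowed for. The comparison of non-Ensembl models with Ensembl rows was chosen after the calls had been seen. The median log2 fold change was 0.06 in non-Ensembl models and -0.01 in Ensembl rows.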

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

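The tests on rows with whole counts alone, on Ensembl rows alone and without the 10 most abundant rows were chosen after the result was seen. The count of 2730 rows stayed within 1.5 times its value under limma-voom, DESeq2, RLE, upper quartile and library-size scaling. It also did so with both count filters, Ensembl rows alone, removal of the 10 most abundant rows and an adjusted p of 0.01. With each library left out in turn it was 1988 to 2759 rows. Rows called both there and in the main fit had the same direction. That is no separate support, since these fits share most or all libraries and the stricter threshold reuses the main fit. Exceptions in size were a fold of at least 2 (867 rows, 489 up and 378 down) and rows with whole counts alone (540 rows, 270 up and 270 down, from 2473 tested), both of which have fewer rows by construction. Falls alone dropped from 1321 to 842 with DESeq2, which also recovered fewer of the simulated changes (cause of the drop not tested) and to 824 at an adjusted p of 0.01, by the stricter threshold. Scaling by library size alone called 2867 rows with 43.0% rises instead of 51.6%, and moved the median log2 fold change of all rows to -0.05. With the replicate block 2960 rows passed, of which 2718 were among the 2730, and no count named here moved by over 1.5 times. Signs of 3 composition differences (KD minus WT), none of which passed its test, turned with single libraries left out: total counts ranged from -117408 to 35581, rows detected from -17.7 to 49.3 and the share of non-Ensembl models from -0.182 to 0.159 percentage points, the cause not tested. The 28 gene lists, the seed-site test and the length correction were not run. In the simulation edgeR recovered 3 of 19 changes of 1.5-fold in rows with a mean count below 50 and 39 of 46 in rows at or above 50.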

Other observations

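The tests of abundance and of whole counts for non-Ensembl models were chosen only after the calls had been seen. The real grouping of the 6 libraries gave 2730 rows past the threshold, and the highest of the other splits into 3 and 3 gave 0 with edgeR and 0 with limma-voom (131 to 586 rows at an unadjusted p under 0.05 with edgeR, against 4077 for the real grouping). Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split put WT and KD libraries on both sides, so the group difference added to the spread within sides. Few calls were therefore to be expected from those splits, and their 0 is no measure of the calls that chance would give.

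Non-Ensembl gene models past the threshold rose more often than they fell, 61.1% against 49.9% in Ensembl rows. This pattern is not established: it did not pass without WT replicate 2 (58.3% against 52.4%, Fisher's exact p = 0.058). The set of all tested models did not pass against the other rows either (limma camera p = 0.18, and p = 0.57 with an estimated correlation). That test has little power for so large a set and does not ask about the share of rises among calls, so it cannot decide the question. The tables argue against the lower abundance of these models as the cause: 10000 draws of Ensembl rows matched on abundance gave 44.8% to 55.7% rises (central 95%), below the observed 61.1%. The draws held 291 to 353 called rows (central 95%), against 422 called non-Ensembl models. At matched abundance the models thus passed more often, so the draws did not equal the models in everything but direction. The draws treat rows as independent, so both ranges are too narrow where rows vary together. Reads shared between rows may still account for the pattern. Among the 67 called non-Ensembl models whose counts were whole numbers in all 6 libraries 58.2% rose (95% exact interval 45.5% to 70.2%), a range that holds both the 47.1% of Ensembl rows with whole counts and the share of all non-Ensembl models. A response of these loci to the knockdown is an open hypothesis that was not tested, since nothing here tells what the models are.

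Changes of at least 8-fold were mostly rises, 54 against 15, or 78.3%. Low counts may be part of this: with a mean count of at least 50 the share was 60.7% of 28 rows (95% exact interval 40.6% to 78.5%), which neither excludes 50% nor the full share. The share was 95.7% (22 against 1) in rows with whole counts and 84.6% (44 against 8) in Ensembl rows alone. With each library left out in turn the share stayed above 60%, the bound set before the test for a single outlying library. Leaving out KD replicate 3 gave the lowest share, 66.2% (95% exact interval 54.6% to 76.6%). That interval lies above 50% but reaches below 60%, so a single outlying library is not excluded. The difference between KD and WT cells that the labels name remains an untested explanation.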
